A study of Mus musculus with 10 samples.

How the data were processed

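Epithelial cells of the mouse proximal jejunum, sorted by a fluorescent reporter and untreated, were profiled by droplet sequencing in 10 libraries of 5 groups, with 2 libraries each. The groups were Bmi1-GFP+, Prox1-GFP+, Lgr5-eGFP+ and Lgr5-eGFP- cells on the Chromium platform (8 libraries, HiSeq4000) and Prox1-GFP+ cells on the GemCode platform (2 libraries, NextSeq500). The deposited matrices hold raw UMI counts per gene and cell barcode for 27998 genes, with 5570 barcodes in total, and whole-number counts were checked in every file. The submitters' processing notes name Cell Ranger and the mm10 assembly. The Cell Ranger version, the rule that called barcodes as cells and the gene annotation release are not given in the sources used here. Per the labels, the GemCode libraries are technical replicates with a shorter UMI, and they were kept out of the tests between groups because platform and group cannot be separated there. They entered the clustering, the shares and the comparison of cell classes within libraries. Positions are from mm10 (GRCm38, GENCODE annotation), where 27645 of 27998 gene IDs were matched (98.7%).

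Barcodes with at least 500 genes and at most 25% mitochondrial UMIs were kept, which left 4813 cells and removed 757 barcodes. Kept cells per library numbered 241 and 428 (Bmi1-GFP+), 221 and 42 (Prox1-GFP+ Chromium), 521 and 537 (GemCode), 666 and 520 (Lgr5-eGFP-) and 744 and 893 (Lgr5-eGFP+). Summed UMIs per library ran from 345826 to 10536636, and the Pearson correlation of log2 CPM between the libraries of a group, across genes, from 0.921 (Prox1-GFP+ Chromium) to 0.993 (Lgr5-eGFP+). Genes are not independent replicates. Counts differed between libraries of a group by 2.82 to 22.7 times the counting variance (chi-square per degree of freedom). Cells were scaled to 10000 UMIs and log-transformed, and 2000 variable genes (mitochondrial genes, Malat1 and the stem panel genes left out, sex-linked genes kept), 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 19 clusters over all libraries together. A cluster was named for a class when at least 3 markers of the class and at least 30% of its list were raised 2-fold in at least 20% of its cells and at least 1 stood among its 10 leading genes. Class names end in -like because classes rest on transcripts alone. Scrublet marked 89 cells (1.85%), which were kept, and an alternative removed them. In Prox1-GFP+ Chromium replicate 2 it marked 9 of 42 cells.

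UMI counts were summed over the kept cells of each library, and cells were not used as replicates. The 8 Chromium libraries were fitted together in edgeR (filterByExpr, TMM, quasi-likelihood F test, 4 residual degrees of freedom), with Benjamini-Hochberg adjusted p under 0.05 as a call. The enteroendocrine-like contrast was fitted on sums over those cells (2 residual degrees of freedom), and enteroendocrine-like against tuft-like cells were fitted within libraries with library as a term. Shares of cells were compared between groups by exact two-sided permutation of the library labels. With 2 libraries against 2 the smallest possible p is 0.333. Intervals of shares are Wilson 95% intervals, and for a count of 0 the limit is that of 3 counts. A fold against a group with 0 UMIs was computed against 3 counts over the group and is a lower bound, and with 1 to 3 UMIs the ratio is given with its counting interval. For shares of cells with a UMI, every cell was thinned to 2000 UMIs at random, and cells below that depth (68 in all) were left out. CPM are UMI counts scaled to a common library total, and those beside fold changes are TMM-scaled, while those of the reporter genes and of the sex-linked and other transcripts that set groups apart are unscaled.

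Gene groups were tested with camera from limma at a preset correlation of 0.01 and with an estimated correlation, and with fry. In each of 4 contrasts 23 of 25 lists could be tested, and the others had fewer than 3 genes measured. Camera called 51 of the 92 tests, and 4 were also called with an estimated correlation, the cycling progenitor and the granule and exocytosis lists in the Bmi1-GFP+ and Prox1-GFP+ comparisons with Lgr5-eGFP+. The lists were written from general knowledge of the tissue before the data were examined, as were the comparisons, the tests, most of the alternatives and the rule for naming genes. That rule names, per contrast, the 8 genes with the largest increase and the 8 with the largest decrease among called genes with an average log2 CPM of at least 5 and no overlap between groups (5 and 5 for a class contrast). It adds the reporter genes, up to 4 called members of each described list with the largest change, and the 12 stem panel genes. Genes that lead clusters were named by rank.

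Some choices were made after the data were seen. The cell filter was set from the quality distributions, before any clustering or test. Clustering all libraries together replaced clustering per platform, which left GemCode clusters without a name, and the naming threshold was set from the cluster tables. Clustering without the leading genes of the enteroendocrine clusters was added after the cluster sizes had been seen.

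The fits were tested on simulated data, with negative binomial counts drawn at the library sizes and dispersions of the real fits and known genes changed 2-fold or 4-fold. Of genes changed 2-fold, 64% were recovered in the Bmi1-GFP+ comparison with Lgr5-eGFP+, 54% in that of Prox1-GFP+ Chromium, 87% in that of Lgr5-eGFP-, 42% between Bmi1-GFP+ and Prox1-GFP+ Chromium, 55.7% in enteroendocrine-like cells and 35.9% between cell classes. Of genes changed 4-fold, 90% to 100% were recovered. False calls were 3.68% to 10.1% of all calls. In these simulations at most 100 genes were changed at each fold, balanced up and down, and all other genes had 1 mean in every group. The real contrasts called up to 7775 of 12169 genes, so these rates need not hold for them. Alternatives tried were DESeq2, limma-voom, RLE size factors, no low-count filter, a replicate block, all 10 libraries in the fit, all deposited barcodes, a stricter filter (1000 genes and 10% mitochondrial), thinning, fits of 2 groups alone, other clustering settings and leaving out each library.

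Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scanpy 1.11.5 with its Scrublet, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Trajectories, reads and reporter fluorescence were not analysed here.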

Results

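The comparisons addressed how cells marked by Bmi1-GFP or Prox1-GFP in the mouse jejunal epithelium relate to Lgr5-eGFP+ stem cells and to the enteroendocrine lineage. Each of 5 groups had 2 libraries, with 669 kept Bmi1-GFP+ cells, 263 Prox1-GFP+ Chromium cells, 1058 Prox1-GFP+ GemCode cells, 1186 Lgr5-eGFP- cells and 1637 Lgr5-eGFP+ cells. Prox1-GFP+ Chromium replicate 2 held 42 of these cells. The median number of UMIs per cell ran from 6195.5 in Bmi1-GFP+ replicate 2 to 10685 in Lgr5-eGFP+ replicate 2. In the Lgr5-eGFP- libraries the filter removed 301 and 269 barcodes and kept 666 and 520, and the kept cells had a median mitochondrial share of 13.2% and 11.7%, against 1.02% to 6.79% in the other libraries. Nothing in the labels says that the Chromium replicates were separate animals, so p-values measure only the spread between these libraries. Values after ± are SDs for levels, over 2 libraries or over the 4 Prox1-GFP+ libraries in the stem panel comparison within libraries, and standard errors for log2 fold changes.

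Transcripts of the reporter genes differed in how well they followed the sort. Lgr5 (chromosome 10, 115450311 to 115587780, mm10), which encodes a receptor of crypt stem cells, averaged 41.9 ± 3.83 CPM in Lgr5-eGFP+ libraries and 1.90 ± 0.0103 in Lgr5-eGFP- libraries, with 20.2 ± 16.3 in Prox1-GFP+ Chromium, 16.8 ± 3.36 in GemCode and 5.14 ± 4.79 in Bmi1-GFP+ libraries. Prox1 (chromosome 1, 190118035 to 190170714) averaged 119 ± 12.3 CPM in Prox1-GFP+ Chromium and 69.4 ± 18.1 in GemCode libraries. Bmi1-GFP+ libraries, sorted for another reporter, held 70.7 ± 4.37 CPM of Prox1, against 1.54 ± 0.0161 in Lgr5-eGFP- and 1.91 ± 0.381 in Lgr5-eGFP+ libraries. Bmi1 (chromosome 2, 18677018 to 18686629) averaged 21.1 ± 3.97 CPM in Bmi1-GFP+ libraries, 32.1 ± 11.9 in Prox1-GFP+ Chromium, 15.2 ± 2.34 in GemCode, 10.3 ± 0.239 in Lgr5-eGFP- and 13.0 ± 0.755 in Lgr5-eGFP+ libraries. These means were taken before any scaling between libraries.

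Enteroendocrine-like cells made up 93.6 ± 0.399% of Bmi1-GFP+ cells (627 of 669), against 0.448 ± 0.317% of Lgr5-eGFP+ cells (7 of 1637). The difference of 93.2 percentage points stood against a combined SD of 0.509, and the exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. Prox1-GFP+ Chromium cells were split between enteroendocrine-like (50.9 ± 2.16%) and tuft-like cells (42.1 ± 5.70%), whereas GemCode cells from the same reporter were 86.0 ± 3.58% tuft-like and 12.2 ± 5.09% enteroendocrine-like. The tuft-like share of the Chromium libraries read 27.1% at a higher clustering resolution and 17.0% with a stricter cell filter, where unnamed cells rose to 17.7% and 12.8%. Tuft-like cells were 0.415 ± 0.587% of Bmi1-GFP+ cells and 0.661 ± 0.174% of Lgr5-eGFP+ cells, a difference of -0.246 points that was smaller than its SD of 0.612 (exact permutation p = 1). Stem-like cells were 45.7 ± 3.03% of Lgr5-eGFP+ cells and 1.41 ± 0.348% of Bmi1-GFP+ cells, a difference of -44.3 points (SD 3.05, exact permutation p = 0.333) that read -29.1 with a 20% mitochondrial limit and -54.6 with the stricter cell filter. Cycling progenitor-like cells made up 31.4 ± 3.91% of Lgr5-eGFP+, 1.60 ± 0.0800% of Lgr5-eGFP- and 0.234% of Bmi1-GFP+ cells. Lgr5-eGFP- cells were 69.2 ± 4.05% enterocyte-like and 8.56 ± 1.49% goblet-like, against 7.45 ± 0.0780% and 7.04 ± 0.302% of Lgr5-eGFP+ cells. A cluster of 307 cells led by Dmbt1, Rbp7 and Gsdmc4 met no naming rule and took 17.0 ± 1.77% of Lgr5-eGFP-, 5.60 ± 0.634% of Lgr5-eGFP+, 1.64% of Prox1-GFP+ Chromium, 1.09% of Bmi1-GFP+ and 0.573% of GemCode cells.

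**Figure D1:**
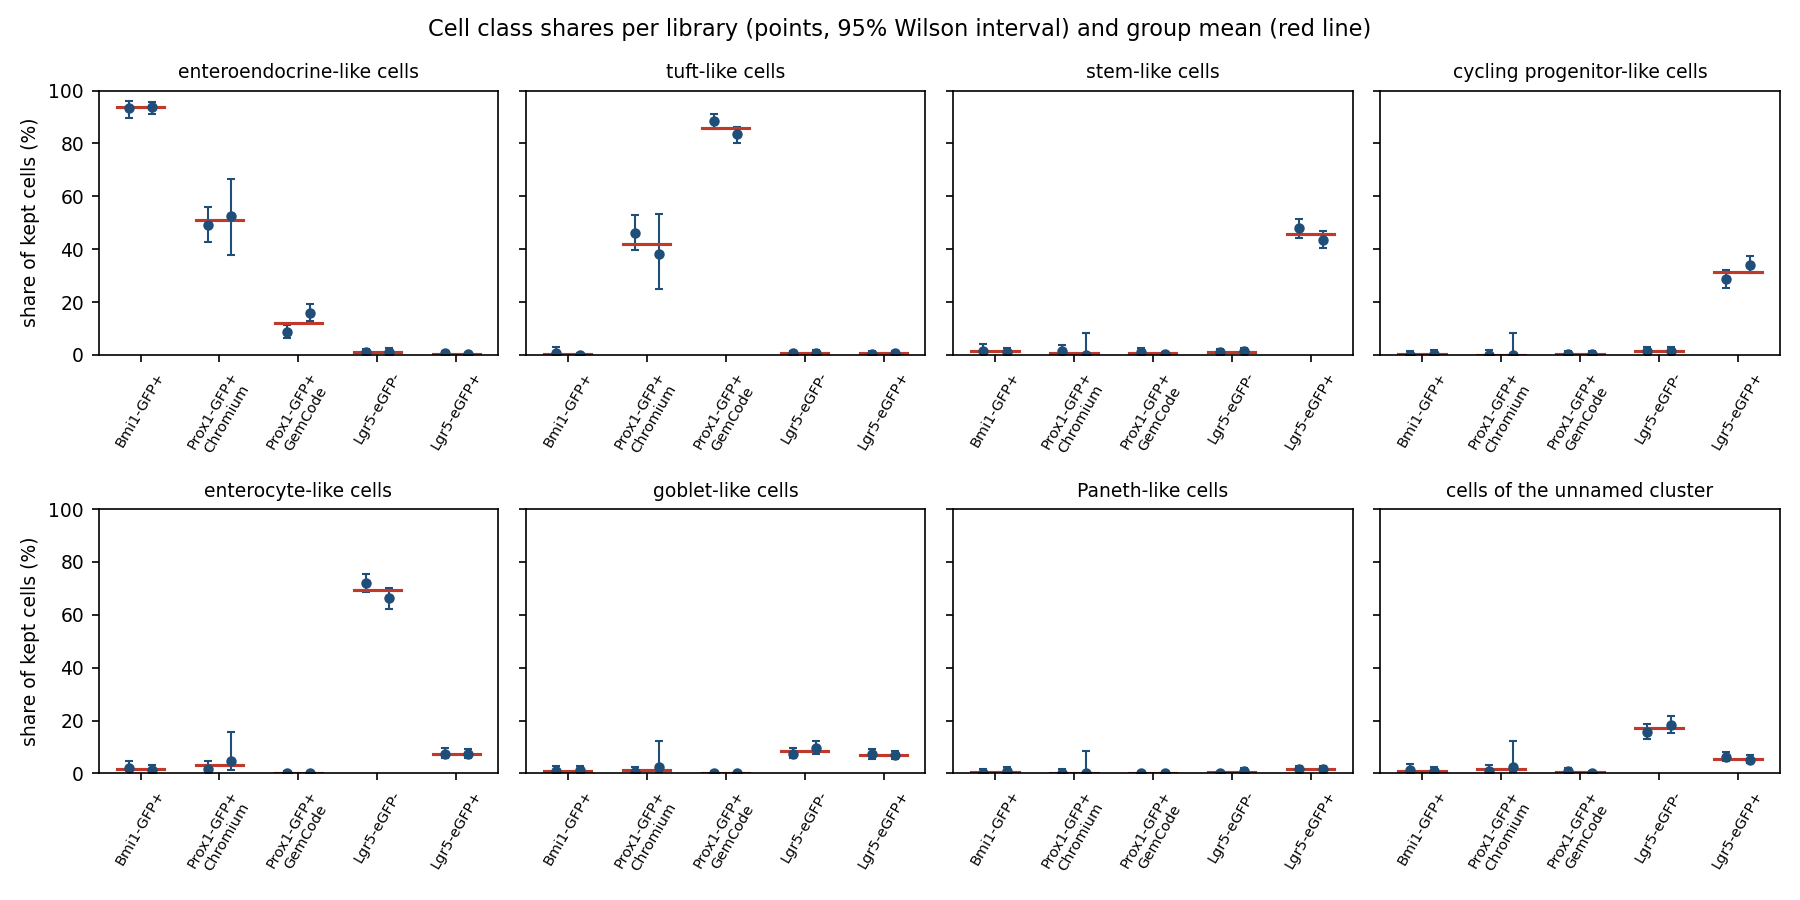
Share of kept cells (%) in each cell class by sorted group, where points are libraries with their 95% Wilson intervals and red lines are group means of 2 libraries. Enteroendocrine-like cells averaged 93.6% in Bmi1-GFP+ and 50.9% in Prox1-GFP+ Chromium libraries, and tuft-like cells averaged 86.0% in Prox1-GFP+ GemCode libraries.

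The Prox1-GFP+ Chromium libraries differed from all others in sex-linked transcripts, which were chosen after their values were seen. Xist (chromosome X, 103460366 to 103483254), transcribed from the inactive X, averaged 2371 ± 12.5 CPM there, 0.351 in Bmi1-GFP+, 0.258 in Lgr5-eGFP- and 0.698 in Lgr5-eGFP+ libraries, with 0 UMIs in GemCode libraries. Y-linked Ddx3y had 0 UMIs in Prox1-GFP+ Chromium libraries (3-count limit 1.22 CPM) and 23.3 to 37.9 CPM elsewhere, and Eif2s3y averaged 0.237 CPM against 29.8 to 57.0. Rpl29 was low on both Prox1-GFP+ platforms, at 81.8 ± 19.3 and 97.1 ± 13.5 CPM, against 656 in Bmi1-GFP+, 1519 in Lgr5-eGFP- and 2898 in Lgr5-eGFP+ libraries. Gm10260 was high on both, at 1054 ± 354 and 349 CPM, against 7.86 to 22.5 elsewhere. H2-Eb1 averaged 3.08 and 10.9 CPM on them, against 39.8 in Bmi1-GFP+, 287 in Lgr5-eGFP- and 221 in Lgr5-eGFP+ libraries. Other MHC class II genes differed less between Prox1-GFP+ Chromium and Bmi1-GFP+ libraries. H2-Aa was at 37.4 ± 7.96 against 43.0 ± 13.2 CPM, Cd74 at 191 ± 61.0 against 262 ± 36.7 and H2-Ab1 at 40.9 ± 21.1 against 91.6 ± 9.88. GemCode libraries had 15.6, 48.3 and 42.5 CPM of these genes. A tuft-like cluster of 148 cells was led by Xist, Pate4 and Gm10260. It held 98 of 102 and 15 of 16 tuft-like cells of the Prox1-GFP+ Chromium libraries, but 13 of 461 and 3 of 448 in GemCode libraries, so tuft-like values set different clusters side by side across platforms. Rac2 was among the leading genes of a further pair of tuft-like clusters. These differences stand beside every Prox1-GFP+ comparison.

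**Figure D2:**
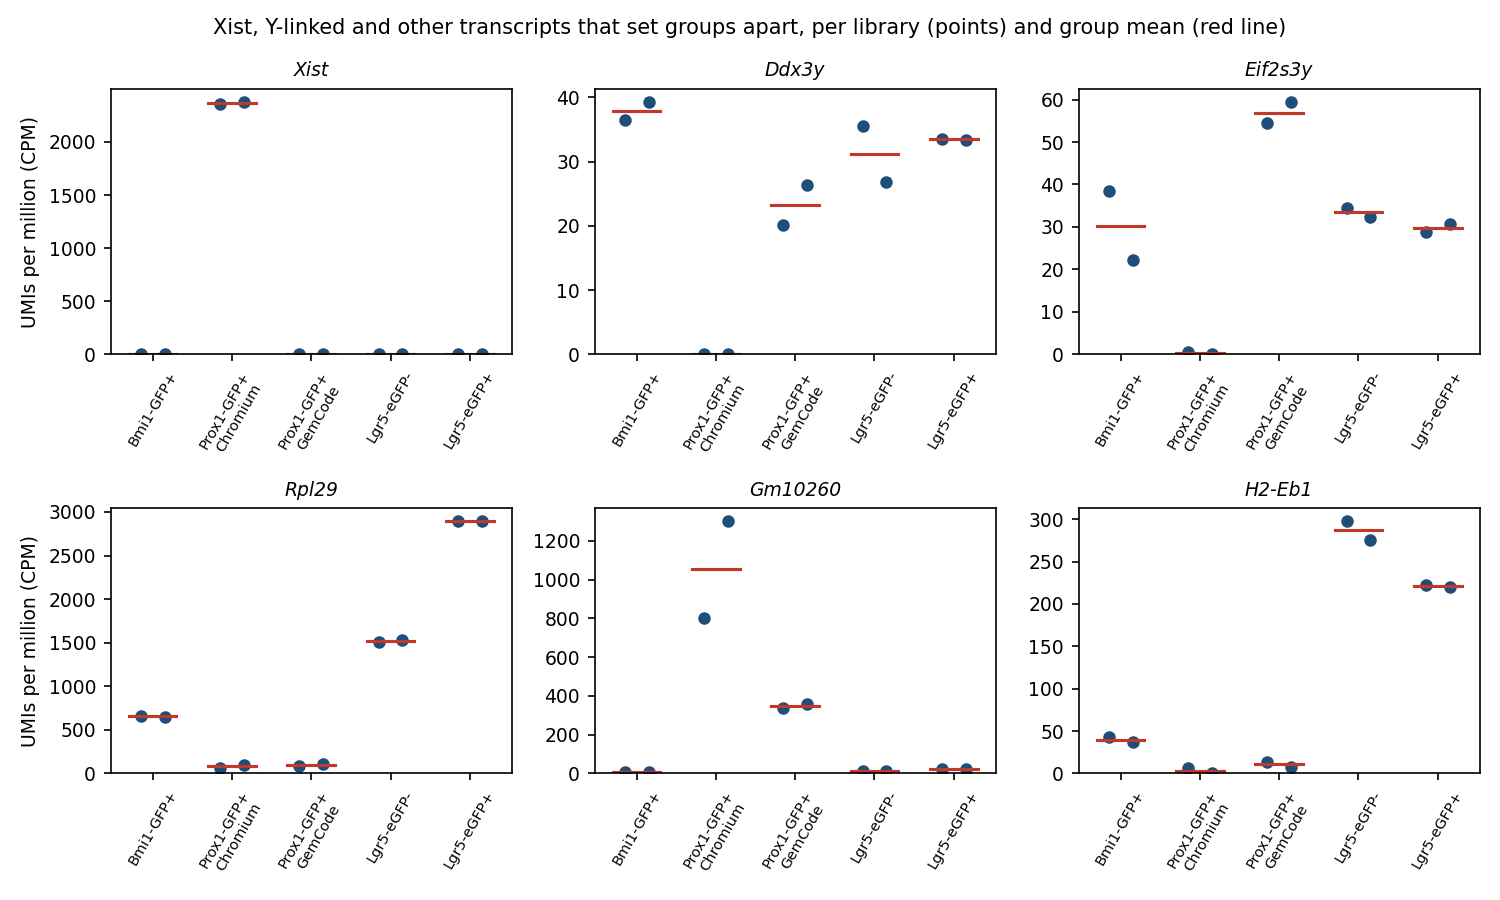
CPM of Xist, Ddx3y, Eif2s3y, Rpl29, Gm10260 and H2-Eb1 in each library (points) with the mean of each sorted group (red lines). Xist averaged 2371 CPM in Prox1-GFP+ Chromium libraries and was at 0 UMIs in GemCode libraries, while Rpl29 averaged 81.8 and 97.1 CPM on these platforms.

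Against Lgr5-eGFP+ libraries, Bmi1-GFP+ libraries carried an endocrine secretory program and little stem-cell or cell-cycle RNA. This and the other whole-library fits compare sums over unlike mixes of cell classes. Their gene and list changes cannot be told from changes in class shares. Somatostatin (Sst) reached 38650.2 ± 6176 CPM against 4.33 ± 0.676, a log2 fold change of 13.11 ± 1.20 (edgeR adjusted p = 1.8e-06), higher in 2 of 2 libraries. Scg2, a granule protein, had 1198 CPM and 0 UMIs in Lgr5-eGFP+ libraries, which made it at least 7898-fold higher. Pyy had 2 UMIs in Lgr5-eGFP+ libraries and a ratio of 11916 with a counting interval of 3297 to 98423. The stem-cell gene Lgr5 was 10.3-fold lower (log2 -3.36 ± 0.37, adjusted p = 8.3e-06), Ascl2 17.9-fold lower (3.6e-08) and Olfm4 37.1-fold lower (4.1e-08). With single libraries left out their log2 changes ran from -4.60 (without Bmi1-GFP+ replicate 1) to -2.40 (without Bmi1-GFP+ replicate 2) for Lgr5, and to -5.67 for Ascl2 and -6.10 for Olfm4 without Bmi1-GFP+ replicate 2. In this fit 7775 of 12169 genes were called, 4259 higher and 3516 lower, and 4853 with cells thinned to 2000 UMIs.

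Of 30 enteroendocrine genes measured, 29 were higher, Neurog3 was lower and 0 were not called, and 30 were called adjusted over the list alone (camera adjusted p = 1.8e-12). With an estimated correlation the enteroendocrine adjusted p was 0.117. All 12 enterochromaffin genes, which serve serotonin cells, were higher, with Reg4 at 13626 against 24.3 CPM, and 12 called adjusted over the list alone (camera 6.8e-08; adjusted p = 0.0612 with an estimated correlation). All 24 granule and exocytosis genes were higher, 24 adjusted over the list alone, including Ptprn at least 664-fold (camera 2.9e-14, and 0.0204 with an estimated correlation). All 20 stem genes were lower, 20 adjusted over the list alone, among them Slc12a2 by 13.9-fold and Cdca7 by 13.5-fold (camera 1.2e-07; adjusted p = 0.117 with an estimated correlation). All 20 cycling progenitor genes were lower, 20 adjusted over the list alone, with Top2a 11.1-fold and Stmn1 9.95-fold lower (camera 3.3e-10, and 0.0227 with an estimated correlation). The endocrine transcription factor Neurod1 (192-fold) was among 10 higher, 2 lower and 1 uncalled of 13 endocrine progenitor genes, 12 called adjusted over the list alone (camera 0.00803; adjusted p = 0.277 with an estimated correlation). Tuft genes showed 3 higher (Kctd12, Matk and Avil), 0 lower and 15 not called of 18, 3 of them adjusted over the list alone. Their median log2 change of 0.12 and mean of 0.25 were positive while camera pointed down (adjusted p = 0.913).

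Signalling and state lists moved as well in the Bmi1-GFP+ comparison, where they too cannot be told from class shares. Of 14 genes on the Wnt target list 12 were lower and 1 was not called. The ligand gene Wnt3, which stood on the list but is not itself a target, was 8.65-fold higher. Adjusted over the list alone 13 were called (camera 0.000614, and 0.184 with an estimated correlation). Of 10 Notch and secretory commitment genes 6 were lower, 2 higher and 2 not called, 8 adjusted over the list alone, with Hes1 5.55-fold lower and the ligand gene Dll4 5.38-fold higher (camera 0.0253; adjusted p = 0.184 with an estimated correlation). All 7 MHC class II genes were lower, 7 adjusted over the list alone, with Cd74 at 255 ± 26.6 against 1351 ± 58.3 CPM (camera 0.000906; adjusted p = 0.184 with an estimated correlation). Dissociation stress genes were higher in 14, lower in 3 (Hspa1a, Hspa1b and Hspa8) and uncalled in 1 of 18, 17 adjusted over the list alone, with Fosb 17.7-fold higher (camera 8.4e-05; adjusted p = 0.0612 with an estimated correlation). Of 22 oxidative phosphorylation genes 17 were lower, 1 higher and 4 not called, 19 adjusted over the list alone, and Cox5a was 3.06-fold lower (camera 6.4e-06; adjusted p = 0.117 with an estimated correlation). Bmi1 itself rose by a log2 of 0.67 ± 0.19 (1.60-fold, adjusted p = 0.00924), and the call was lost with DESeq2 (0.0886), without Bmi1-GFP+ replicate 2 (0.295) and without Lgr5-eGFP+ replicate 2 (0.0793). Prox1 was 34.3-fold higher (log2 5.10 ± 0.16, adjusted p = 4.5e-10). Of 11 stem panel genes 8 were lower, Bmi1, Hopx and Prox1 were higher and 0 were not called, 11 adjusted over the list alone (camera 0.0300; adjusted p = 0.158 with an estimated correlation). Enterocyte genes went both ways, with 12 lower, 5 higher and 3 not called of 20, 18 adjusted over the list alone (camera 0.0803), as Apoa4 fell 4.66-fold and Sis and Krt20 rose 11.2-fold and 9.59-fold. Of 4 enteric neuron and glia genes 3 were higher and 1 was not called, 3 adjusted over the list alone, with Uchl1 at least 127-fold higher (camera 0.00528; adjusted p = 0.117 with an estimated correlation). None of 17 Paneth genes was called, 0 adjusted over the list alone, their median of -0.04 and mean of 0.32 differed in sign and camera pointed down (adjusted p = 0.141). Defa24 read 7288 ± 10296 CPM in Bmi1-GFP+ libraries, where the Paneth list took 0.00804% of UMIs in replicate 1 and 3.61% in replicate 2, and alpha-defensin values are uncertain since these paralogs share reads.

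Prox1-GFP+ Chromium libraries combined endocrine and tuft transcripts. Ghrelin (Ghrl) reached 48175 ± 12971 CPM against 19.9 ± 22.7 in Lgr5-eGFP+ libraries (log2 11.25 ± 0.96, adjusted p = 2.1e-06), and Cck reached 39016 ± 9957 CPM against 28.9 (log2 10.40 ± 0.81, adjusted p = 9.9e-07). Both levels in Lgr5-eGFP+ libraries were uneven, and the log2 changes were 13.62 and 12.33 without Lgr5-eGFP+ replicate 1 and 10.39 and 9.60 without Lgr5-eGFP+ replicate 2. The tuft-cell gene Matk was 193-fold higher. Scg2 was at least 5687-fold higher. Olfm4 had 1 UMI in the Prox1-GFP+ libraries, a ratio of 98.5 with a counting interval of 17.6 to 3894 in favour of Lgr5-eGFP+. Calls were made for 6015 of 12169 genes, 3042 higher and 2973 lower, for 2889 with thinned cells and for 2543 without Prox1-GFP+ Chromium replicate 1.

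Of 30 enteroendocrine genes 27 were higher, Neurog3 was lower and 2 were not called, 28 adjusted over the list alone (camera 6.9e-13; adjusted p = 0.165 with an estimated correlation), and the Neurog3 call was lost without Prox1-GFP+ Chromium replicate 1 (0.349). All 18 tuft genes were higher, 18 adjusted over the list alone (camera 1.2e-08; adjusted p = 0.290 with an estimated correlation). All 24 granule and exocytosis genes were higher, 24 adjusted over the list alone (camera 1.5e-15, and 0.0172 with an estimated correlation). The enterochromaffin list differed from that in Bmi1-GFP+ cells, with 8 higher, Reg4 lower and 3 not called of 12, 9 adjusted over the list alone (camera 0.00469; adjusted p = 0.169 with an estimated correlation). Of the 20 stem genes 19 were lower and 1 was not called, 19 adjusted over the list alone, with Cdca7 10.1-fold lower (camera 1.0e-06; adjusted p = 0.169 with an estimated correlation). All 20 cycling progenitor genes were lower, 20 adjusted over the list alone (camera 1.2e-08, and 0.0324 with an estimated correlation). Among 14 genes on the Wnt target list, Nkd1 (6.81-fold) and the ligand gene Wnt3 were higher and 12 were lower, 14 adjusted over the list alone (camera 0.00477, and 0.285 with an estimated correlation). All 7 MHC class II genes were lower, 7 adjusted over the list alone, with Cd74 7.83-fold lower (camera 0.000109; adjusted p = 0.183 with an estimated correlation). Dissociation stress genes were higher in 14 of 18, with Junb up 9.41-fold, lower in 1 and uncalled in 3, 15 adjusted over the list alone (camera 1.2e-05; adjusted p = 0.0554 with an estimated correlation). Ptprc (at least 74.9-fold) and Rac2 (123-fold, log2 8.21 without Lgr5-eGFP+ replicate 2) were among 3 higher and 2 uncalled of 5 genes on the immune list, 3 adjusted over the list alone, and the list was not called (camera 0.0731). No cluster was named for the immune class, and Rac2 also stood among the leading genes of tuft-like clusters. Its rise thus does not tell immune from tuft-like cells. Prox1 rose by a log2 of 5.64 ± 0.17 (adjusted p = 1.0e-09) and Bmi1 by 0.82 ± 0.23 (0.0109), the Bmi1 call being lost with thinned cells (0.45). Lgr5 was 1.73-fold lower (log2 -0.79 ± 0.29, adjusted p = 0.0392), a call lost with DESeq2 (0.101), with limma-voom (0.0546), with thinned cells (0.288), with all deposited barcodes (0.0508) and without any single library (0.051 to 0.138). The Lgr5 levels of the Prox1-GFP+ Chromium replicates were 31.7 and 8.67 CPM, and the log2 change was -2.50 without replicate 1. Paneth genes were lower in 8 and uncalled in 9 of 17, 11 adjusted over the list alone (camera 0.00566; adjusted p = 0.519 with an estimated correlation). The Defa24 call among them was lost with limma-voom (0.24) and without Prox1-GFP+ Chromium replicate 1 (0.211) or replicate 2 (0.0833).

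Lgr5-eGFP- libraries differed from Lgr5-eGFP+ libraries by absorptive genes. Apoa4, an apolipoprotein gene of absorptive cells, was at 11839 ± 1947 CPM against 621 ± 197 (log2 4.25 ± 0.24, adjusted p = 3.9e-08). Cd36, which takes up fatty acids, was 22.1-fold higher and the disaccharidase gene Treh 17.0-fold higher. Lgr5 was 19.8-fold lower (log2 -4.31 ± 0.33, adjusted p = 4.3e-07), Ascl2 13.9-fold and Gkn3 22.0-fold lower. Of 12169 genes 7607 were called, 3852 higher and 3755 lower, and with the stricter cell filter 4823.

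All 20 enterocyte genes were higher, 20 adjusted over the list alone (camera 1.4e-12; adjusted p = 0.173 with an estimated correlation), as were 14 of 15 lipid absorption genes, 14 adjusted over the list alone, with 1 not called (camera 1.3e-09; adjusted p = 0.173 with an estimated correlation). All 20 stem genes were lower, 20 adjusted over the list alone (camera 1.3e-08; adjusted p = 0.173 with an estimated correlation), and so were all 20 cycling progenitor genes, 20 adjusted over the list alone, with Stmn1 4.80-fold lower (camera 5.8e-07; adjusted p = 0.10 with an estimated correlation). Genes on the Wnt target list were lower in 13 and uncalled in 1 of 14, 13 adjusted over the list alone (camera 1.6e-05, and 0.173 with an estimated correlation). Among them Cd44 was 5.60-fold lower, and at a log2 of -3.12 without Lgr5-eGFP- replicate 1. Enteroendocrine genes were higher in 19, lower in 1 (Pax4) and uncalled in 10 of 30, 21 adjusted over the list alone (camera 3.3e-05; adjusted p = 0.291 with an estimated correlation). Among them Sct was 37.6-fold higher, and enteroendocrine-like cells were 1.18% of Lgr5-eGFP- cells. The Pax4 call was lost with DESeq2 (0.076), with the stricter filter (0.0913), without Lgr5-eGFP- replicate 1 (0.118) and without Lgr5-eGFP+ replicate 2 (0.0587). Goblet genes were higher in 9, lower in 2 and uncalled in 3 of 14, 11 adjusted over the list alone, with Muc2 7.97-fold higher (adjusted p = 0.000822), while the list was not called (camera 0.108). MHC class II genes were higher in 7 of 7, 7 adjusted over the list alone (camera 0.0340; adjusted p = 0.365 with an estimated correlation). Their H2-Aa rise of 2.94-fold and H2-Ab1 rise of 2.93-fold were not called with the stricter cell filter (adjusted p = 0.947 and 0.462), nor were H2-DMb1 (0.535) and Ciita (0.685). Ciita was also not called with DESeq2 (0.124), without Lgr5-eGFP- replicate 1 (0.166) and without Lgr5-eGFP+ replicate 2 (0.0532). Oxidative phosphorylation genes were higher in 18 and uncalled in 4 of 22, 19 adjusted over the list alone (camera 0.000194; adjusted p = 0.173 with an estimated correlation). Regeneration-associated Anxa2 and Areg were 8.51-fold and 11.3-fold higher in a list of 7 with 3 higher, 2 lower and 2 not called, 6 adjusted over the list alone (camera 0.278). Bmi1 (log2 -0.19 ± 0.18, adjusted p = 0.379) and Prox1 (log2 -0.20 ± 0.33, adjusted p = 0.691) were not called.

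Bmi1-GFP+ libraries carried more enterochromaffin and less tuft RNA than Prox1-GFP+ Chromium libraries. Reg4 was at 13626 ± 2059 CPM against 12.3 ± 0.539 (log2 10.13 ± 0.24, adjusted p = 9.0e-10), Chga was 16.0-fold higher (5.1e-08) and Cartpt at least 316-fold higher. Sst was 51.6-fold higher (log2 5.69 ± 0.89, adjusted p = 0.000866), with a log2 of 7.59 and 4.90 without Prox1-GFP+ Chromium replicates 1 and 2. In the Prox1-GFP+ direction, the tuft-cell channel gene Trpm5 was 142-fold (3.4e-07) and the tuft marker Dclk1 69.5-fold (1.3e-05) lower in Bmi1-GFP+ libraries. Their log2 changes were -9.40 and -9.91 without Bmi1-GFP+ replicate 1 and -5.97 and -4.82 without Bmi1-GFP+ replicate 2. The glucagon gene Gcg was 16.5-fold lower (log2 -4.04 ± 0.87, adjusted p = 0.00622). Of 12169 genes 2912 were called, 1729 higher and 1183 lower, with 1037 called in thinned cells and 1936 without Bmi1-GFP+ replicate 2. The excess of higher calls was not stable, with 928 higher and 917 lower of 1845 by DESeq2, 1390 and 1378 with all 10 libraries in the fit, 1468 and 1412 with all deposited barcodes, and 280 and 334 of 614 without Prox1-GFP+ Chromium replicate 1.

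All 12 enterochromaffin genes were higher, 12 adjusted over the list alone (camera 2.7e-08; adjusted p = 0.0692 with an estimated correlation), including Lmx1a, which was at least 39.6-fold higher. All 18 tuft genes were lower, 18 adjusted over the list alone (camera 6.1e-15; adjusted p = 0.240 with an estimated correlation). Granule and exocytosis genes were higher in 17 and uncalled in 7 of 24, 22 adjusted over the list alone, with Ptprn 6.89-fold higher (camera 4.1e-07; adjusted p = 0.0692 with an estimated correlation). Enteroendocrine genes were higher in 18, lower in 1 (Gcg) and uncalled in 11 of 30, 24 adjusted over the list alone (camera 0.000470; adjusted p = 0.415 with an estimated correlation). Peptide hormone genes went both ways, with Sct, Gip, Sst, Iapp, Tac1 and Ucn3 higher, Gcg, Gal and Gast lower and 4 of 13 not called, 10 adjusted over the list alone (camera 0.425). Gip was 67.9-fold higher (adjusted p = 0.0229), DESeq2 did not call it (0.0697), and its level of 512 ± 724 CPM in Prox1-GFP+ Chromium libraries was smaller than its SD. Cycling progenitor genes were lower in 6 and uncalled in 14 of 20, 6 adjusted over the list alone (camera 6.4e-05; adjusted p = 0.0692 with an estimated correlation). Stem panel genes were lower in 5 (Lgr5, Ascl2, Smoc2, Sox9 and Prox1) and uncalled in 6 of 11, 7 adjusted over the list alone (camera 0.0478; adjusted p = 0.240 with an estimated correlation). Sox9 was 6.54-fold lower (log2 -2.71 ± 0.14, adjusted p = 3.1e-07). The Lgr5 call (5.94-fold lower, adjusted p = 0.00346) was lost without Prox1-GFP+ Chromium replicate 1 (0.79). The Prox1 call (1.46-fold lower, 0.00872) was lost there too (0.126), with thinned cells (0.0865) and with DESeq2 (0.0518). Bmi1 transcripts did not differ detectably (log2 -0.14 ± 0.25, adjusted p = 0.762). Nkd1, a Wnt target, was 35.7-fold lower, with a log2 of -6.42 and -4.20 without Bmi1-GFP+ replicates 1 and 2. It was also among the leading genes of the tuft-like cluster of 148 cells, and Bmi1-GFP+ libraries held 2 and 0 tuft-like cells. Dissociation stress genes were higher in 12, lower in 2 and uncalled in 4 of 18, 16 adjusted over the list alone, with Hspb1 at 61.5 against 4.44 CPM (camera 0.0146; adjusted p = 0.194 with an estimated correlation). Paneth genes were higher in 4 and uncalled in 13 of 17, 10 adjusted over the list alone, and the list was not called (camera 0.112) except with a replicate block (camera 0.0405). The Defa24 call among them reversed to a log2 of -1.57 without Bmi1-GFP+ replicate 2. Immune genes were lower in 3, higher in 1 and uncalled in 1 of 5, 4 adjusted over the list alone. This list was not called either (camera 0.0563), but it was with a replicate block (camera 0.0494).

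Within enteroendocrine-like cells alone, 631 of 8489 genes differed between Bmi1-GFP+ and Prox1-GFP+ Chromium libraries, 391 higher and 240 lower. Gcg was at 189 ± 0.980 CPM against 4949.6 ± 299.7 (log2 -4.71 ± 0.20, adjusted p = 1.7e-11). Gcg was a leading gene of the Pyy cluster, which held 5.10% of Bmi1-GFP+ and 22.9% of Prox1-GFP+ Chromium enteroendocrine-like cells, and within the Cck cluster alone its log2 change was -3.54 (adjusted p = 5.0e-19). Reg4 was 611-fold higher (log2 9.26 ± 0.45, adjusted p = 1.3e-10), Afp at least 397-fold, Cartpt at least 159.9-fold, the noncoding RNA Meg3 at least 39.1-fold and Tpbg at least 32.6-fold higher. All 27 Reg4 UMIs of the Prox1-GFP+ Chromium cells lay in replicate 1. Reg4, Afp and Cartpt also led the Tph1 cluster, which held 199 of 627 Bmi1-GFP+ and 0 of 131 Prox1-GFP+ Chromium cells, while the Cck cluster was the largest in both groups (215 and 72 cells). Within the Cck cluster Reg4 was still higher (log2 6.57, adjusted p = 4.4e-24), as were Afp (1.4e-11) and Cartpt (8.9e-08), and free RNA from cells of other clusters was not tested there. Xist had 2 UMIs in Bmi1-GFP+ enteroendocrine-like cells, a ratio of 4259.9 with a counting interval of 1178 to 35195 toward Prox1-GFP+. The calls for Fxyd2 (4.81-fold lower), Tspan8 (4.31-fold lower) and Cyba (3.87-fold lower) were lost without Prox1-GFP+ Chromium replicate 1, with adjusted p of 0.685, 0.911 and 0.129. DESeq2 did not call Tspan8 (0.0694). Meg3 was a leading gene of the Sst cluster, which held 111 of 627 Bmi1-GFP+ and 2 of 131 Prox1-GFP+ Chromium cells. Fxyd2 was a leading gene of the Ghrl cluster, with 2.07% and 19.1% of these cells. Meg3, Tpbg and Fxyd2 were not fitted within the Cck cluster, so their changes cannot be told from cluster shares. The number of called genes was 131 with DESeq2, 127 without Prox1-GFP+ Chromium replicate 1, 313 and 369 without Bmi1-GFP+ replicates 1 and 2, and 135 of 5489 within the Cck cluster alone, an alternative chosen after seeing the data. A like comparison of tuft-like cells gave no value, since Bmi1-GFP+ libraries held 2 and 0 such cells.

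The 6 enteroendocrine clusters were named by Tph1, Sst, Cck, Gip, Pyy and Ghrl, each among its leading genes. Because those genes differ between the groups, cells were clustered again without the 56 leading genes, a step chosen after seeing the data. Xist and Gm10260, which also differ between groups, were not among the genes left out. New clusters were named by the earlier cluster that gave most of their enteroendocrine-like cells. The repeat is thus not independent of the first clustering, and its clusters may still follow the sorted group. Bmi1-GFP+ cells then filled the Tph1 cluster with 217 of 627 cells (34.6%, Wilson 95% interval 31.0 to 38.4%) and the Sst cluster with 111 (17.7%, 14.9 to 20.9%). Prox1-GFP+ Chromium cells gave 0 of 127 in the Tph1 cluster (3-count limit 2.36%) and 2 in the Sst cluster (1.57%, 0.433 to 5.56%). GemCode cells gave 0 of 130 (limit 2.31%) and 1 (0.769%, 0.136 to 4.23%). The Cck cluster held 31.9% of Bmi1-GFP+ cells (28.4 to 35.6%), 55.1% of Prox1-GFP+ Chromium cells (46.4 to 63.5%) and 71.5% of GemCode cells (63.3 to 78.6%). The Gip cluster held 9.09% of Bmi1-GFP+ (7.08 to 11.6%), 0.787% of Prox1-GFP+ Chromium (0.139 to 4.33%) and 16.2% of GemCode cells (10.8 to 23.4%). The Pyy cluster held 6.70% of Bmi1-GFP+ (4.99 to 8.93%), 42.5% of Prox1-GFP+ Chromium (34.3 to 51.2%) and 11.5% of GemCode cells (7.12 to 18.2%). The Ghrl cluster, with 2.07% of Bmi1-GFP+ and 19.1% of Prox1-GFP+ Chromium cells at first, did not stand apart without the leading genes, and 57.9% of the new Pyy cluster came from the earlier Pyy cluster.

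**Figure D3:**
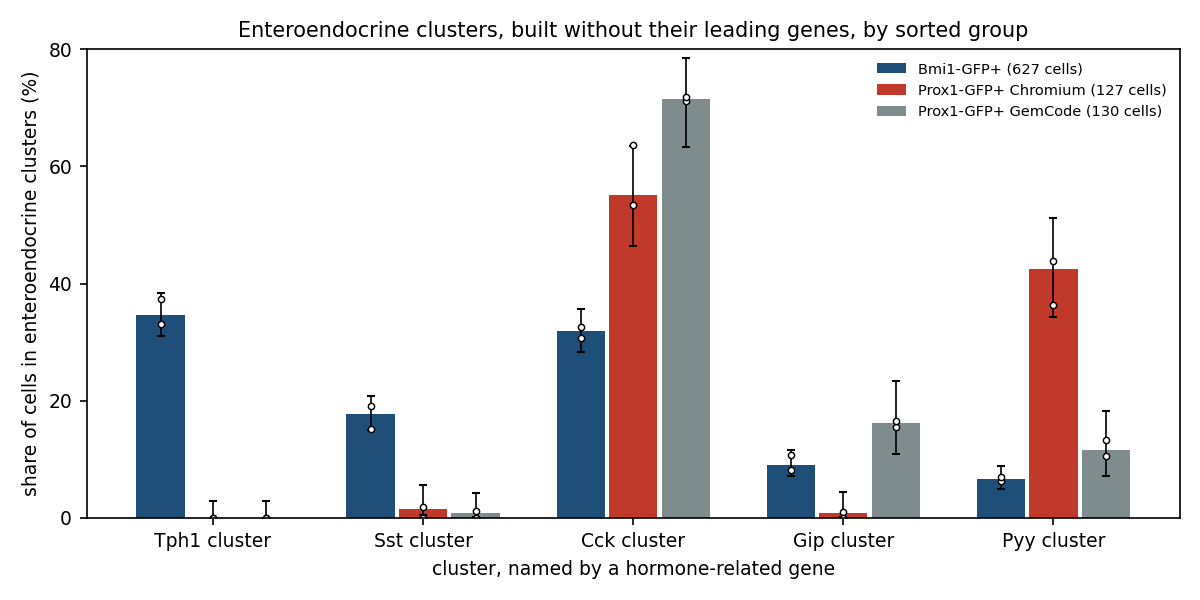
Share (%) of cells in each enteroendocrine cluster built without the leading genes, with bars for the 627 Bmi1-GFP+, 127 Prox1-GFP+ Chromium and 130 Prox1-GFP+ GemCode cells, black lines for 95% Wilson intervals and white circles for libraries. The Tph1 cluster held 34.6% of Bmi1-GFP+ cells and 0 cells of either Prox1-GFP+ group.

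Stem panel genes were split between endocrine and tuft cells. Within the 4 Prox1-GFP+ libraries, Axin2 (chromosome 11, 108920349 to 108950783), a Wnt target, was at 58.9 ± 22.2 CPM in enteroendocrine-like and 9.68 ± 9.44 in tuft-like cells (log2 3.67 ± 0.64, adjusted p = 0.00111), higher in 4 of 4 libraries, with a log2 of at least 2.95 without either GemCode replicate. The Axin2 fold was larger in GemCode libraries (84.9 against 2.13 and 61.5 against 1.56 CPM) than in Chromium libraries (58.6 against 14.2, and 30.6 against 20.8 from 4 and 3 UMIs), and the Chromium libraries alone gave a log2 of 1.77 (adjusted p = 0.000389). Sox9 (chromosome 11, 112782224 to 112787760) was at 31.8 ± 26.2 against 341 ± 41.5 CPM (log2 -3.14 ± 0.37, adjusted p = 7.2e-05), Ascl2 (chromosome 7, 142966829 to 142969264) at 5.15 ± 4.36 against 59.7 ± 7.09 (log2 -3.46 ± 0.44, 0.000118) and Lgr5 at 2.20 ± 4.39 against 27.2 ± 17.0 (log2 -3.13 ± 0.60, 0.00211). Prox1 (log2 0.57 ± 0.20) was not called over all 6419 genes (0.0523) and was called adjusted over the list alone (0.0259), so 4 panel genes were called over all genes and 5 over the list alone. Bmi1 (0.984), Hopx (0.619) and Smoc2 (0.198) were not called, and Olfm4, Lrig1, Tert and Mex3a had too few counts. Without Prox1-GFP+ Chromium replicate 1 the calls numbered 2, Ascl2 and Sox9, of 4 panel genes measured there, against 8 measured in the full fit. Axin2 and Lgr5 were not among those 4, so they were not tested. By their labels the GemCode pair are technical replicates, so these 4 libraries stand for fewer than 4 separate samples. In the Chromium libraries alone 6 panel genes were called, adding Prox1 (log2 0.74, adjusted p = 0.00858) and Smoc2 (log2 -1.80, adjusted p = 6.8e-05). That fit, also used for Axin2 above, had only 2 libraries, and replicate 2 held 22 enteroendocrine-like and 16 tuft-like cells. The p-values of that fit rest mostly on spread shared across genes and little on spread between these libraries. Smoc2 was also called in all 4 libraries without the low-count filter (0.032). Smoc2 read opposite ways by platform, at 23.4 and 7.65 CPM in enteroendocrine-like against 60.4 and 118 in tuft-like cells of the Chromium libraries, and at 15.9 and 14.0 against 9.06 and 9.38 in the GemCode libraries. The enteroendocrine-like values came from 16 and 1 UMIs in Chromium and from 3 and 5 UMIs in GemCode libraries. The GemCode direction may thus be counting error. Bmi1 also read opposite ways, at 36.6 and 76.5 against 20.4 and 27.7 CPM in Chromium and at 5.30 and 0 against 13.9 and 17.7 in GemCode libraries. Its enteroendocrine-like values came from 25 and 10 UMIs in Chromium and from 1 and 0 UMIs in GemCode libraries. A difference between platforms was not tested for either gene.

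In single cells thinned to 2000 UMIs, Prox1 had a UMI in 15.4% of 852 enteroendocrine-like cells (Wilson 95% interval 13.1 to 18.0%) and 11.8% of 1041 tuft-like cells, against 0 of 962 enterocyte-like cells (3-count limit 0.312%), which served as background. Of the 965 enterocyte-like cells before thinning, 825 came from Lgr5-eGFP- and 11 from Bmi1-GFP+ libraries, so this background does not measure free RNA in the Bmi1-GFP+ and Prox1-GFP+ libraries. Most enteroendocrine-like and tuft-like cells were sorted on Bmi1-GFP or Prox1-GFP, and most background cells were not. Higher shares of Prox1 and Bmi1 than in the background can thus come in part from the sort. Hopx (chromosome 5, 77086988 to 77115121) was found in 10.6% (8.67 to 12.8%) of enteroendocrine-like cells against 0.520% in the background, Axin2 in 5.75% (4.38 to 7.52%) against 1.04%, and Sox9 in 3.29% (2.28 to 4.71%) against 1.04%. Bmi1 was found in 4.34% (3.17 to 5.93%) against 2.18%. Lgr5 was found in 0.352% (0.120 to 1.03%) against 0.208% in the background, and in 11.8% of 779 stem-like and 4.32% of tuft-like cells. The 3 enteroendocrine-like cells with Lgr5 were all Prox1-GFP+ Chromium cells, 2.34% of 128 (0.80 to 6.66%, and 3.91% unthinned), against 0 of 579 Bmi1-GFP+ (3-count limit 0.518%) and 0 of 124 GemCode cells (limit 2.42%). All 6 unthinned Lgr5 UMIs lay in Prox1-GFP+ Chromium replicate 1, whose tuft-like cells held 59, and free RNA was not tested there. Sox9 was in 44.1% and Ascl2 in 11.4% of tuft-like cells. Median depths were 6145 UMIs in enteroendocrine-like, 7786 in tuft-like, 8937 in stem-like and 7012.5 in enterocyte-like cells. Thinning left out 57 of 909 enteroendocrine-like, 7 of 1048 tuft-like, 3 of 965 enterocyte-like and 0 of 779 stem-like cells. Unthinned, the enteroendocrine-like and background shares were 37.4% and 0 for Prox1, 30.2% and 2.70% for Hopx, 19.2% and 5.30% for Axin2, 13.6% and 6.65% for Bmi1, 10.7% and 3.95% for Sox9, and 0.704% and 0.520% for Lgr5. The intervals and 3-count limits cover counting error only.

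**Figure D4:**
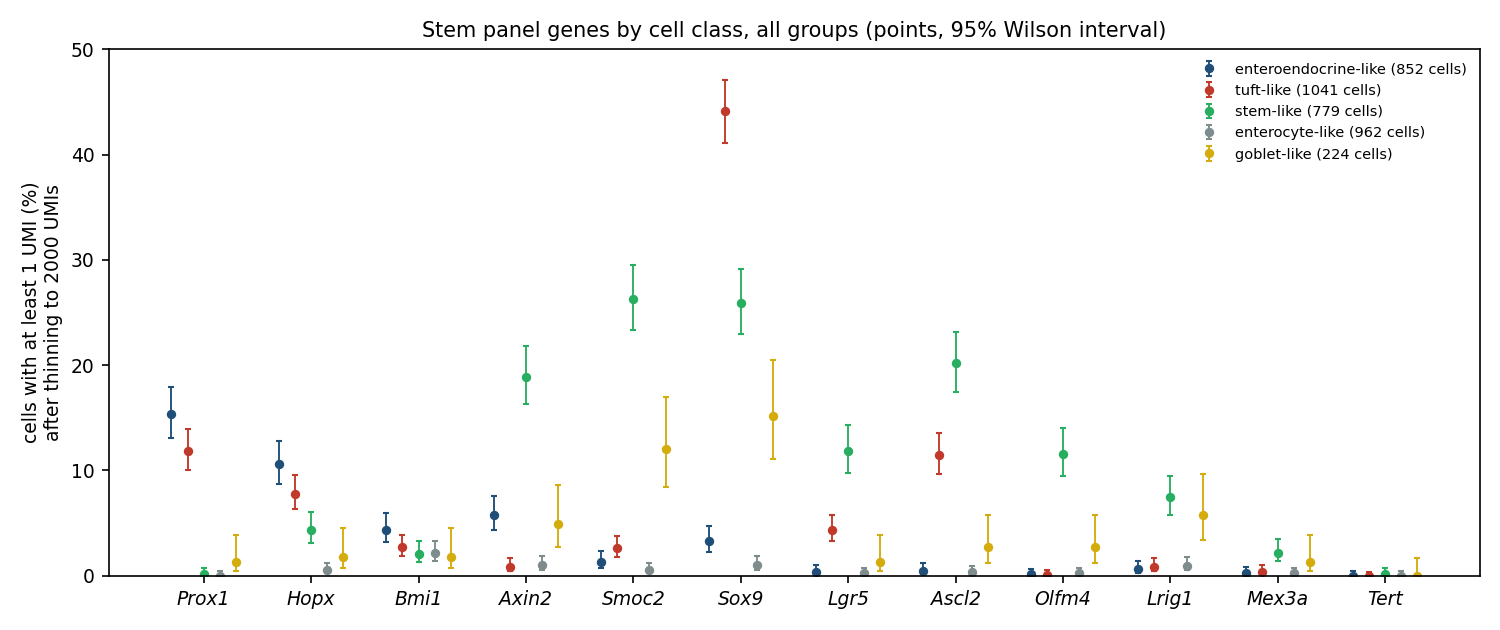
Share of cells (%) with at least 1 UMI of each of the 12 stem panel genes after thinning every cell to 2000 UMIs, by cell class, with 95% Wilson intervals. Prox1 was found in 15.4% of enteroendocrine-like and 11.8% of tuft-like cells, Sox9 in 44.1% of tuft-like cells and Lgr5 in 11.8% of stem-like cells.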

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

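The fit within the Cck cluster, the clustering of Chromium libraries alone and the 20% mitochondrial limit were tests chosen only after the result was seen. So were clustering with 30 neighbours and looser rules for naming clusters. Counts of called genes stayed within 1.5 times the reported count in 78 of 94 alternative values, named genes kept direction and call in 4656 of 4887, and lists in 133 of 184. Settings in which a named gene was not measured are not among these values. Shares were less stable. Class shares per group moved by their SD or more in 165 of 432 values. Shares of cells with a UMI left their interval in 16 of 24 when thinned to 1000 UMIs. Thinning to 2000 UMIs, which lowers the counts behind every gene, gave 4853 called genes for Bmi1-GFP+ and 2889 for Prox1-GFP+ Chromium against Lgr5-eGFP+, and 1037 between these groups. The stricter cell filter gave 4823 for Lgr5-eGFP- against Lgr5-eGFP+, and the cause was not tested. DESeq2 gave 1845 between Bmi1-GFP+ and Prox1-GFP+ Chromium and 131 in enteroendocrine-like cells, and the Cck cluster alone, with fewer cells, gave 135. Replicate differences correlated at 0.696 over 3524 genes between Bmi1-GFP+ and Lgr5-eGFP-, and at -0.0423 to 0.128 for the 5 other pairs of groups. In Bmi1-GFP+ and Lgr5-eGFP- libraries the Paneth list took 0.00804% and 0.0265% of UMIs in replicate 1, against 3.61% and 2.78% in replicate 2. Paneth genes were not left out of the correlation, so whether replicate numbers pair those groups stays open. A replicate block gave 7710, 5826, 7499 and 2660 for the 4 contrasts, 525 in enteroendocrine-like cells and 53 called list tests. With an estimated correlation 4 of 51 list calls held.

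Leaving out single libraries, with a lone library assumed to vary like the other groups, gave 6004 to 7069, 2543 to 5759, 6239 to 6792 and 614 to 2820 called genes in the 4 contrasts in the same order, 127 to 736 in enteroendocrine-like cells and 2 to 4 panel genes. The lowest values, 2543, 614, 127 and 2, all came without Prox1-GFP+ Chromium replicate 1, which leaves 42 cells in its group. The count between Bmi1-GFP+ and Prox1-GFP+ Chromium was 1936 without Bmi1-GFP+ replicate 2, and the enteroendocrine-like count was 313 and 369 without Bmi1-GFP+ replicates 1 and 2. The share differences between Bmi1-GFP+ and Lgr5-eGFP+ then ran from 92.9 to 93.5 points for enteroendocrine-like, -0.661 to 0.169 for tuft-like and -46.4 to -42.1 for stem-like cells. The enteroendocrine-like difference was 87.7 with all barcodes and 94.2 with the stricter filter. The stem-like difference was -41.0 with panel genes among the clustering features, -38.3 with all barcodes, -54.6 with the stricter filter, -41.2 without Scrublet-marked cells, -40.9 for Chromium alone and -29.1 with the 20% limit. The tuft-like difference reversed to 0.151 at resolution 2 and to 0.169 without Bmi1-GFP+ replicate 2. Leaving out a library moved the fitted fold of 127 of 325 called named results by over 1.5 times in at least 1 fit. The log2 change of Trpa1 in Prox1-GFP+ Chromium against Lgr5-eGFP+ reversed to -1.61 (adjusted p = 0.949) without Prox1-GFP+ Chromium replicate 1 and ran up to 6.46 without others. That of Defa24 in Bmi1-GFP+ against Prox1-GFP+ Chromium reversed to -1.57 (adjusted p = 0.677) without Bmi1-GFP+ replicate 2 and ran up to 9.30. The cause was not tested for these shares and genes. The planned tuft-like contrast and its alternatives were not run, since Bmi1-GFP+ libraries held 2 and 0 tuft-like cells. Lgr5 in enteroendocrine-like cells of all groups together was not separated from background at 2000 UMIs (0.352% against 0.208%) or at full depth (0.704% against 0.520%), while Prox1-GFP+ Chromium cells alone gave 2.34% and 3.91%.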

Other observations

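The tests of cell number, of the largest share that removed barcodes could hold, of free RNA, of doublets and of different animals were chosen only after the result was seen. Paneth transcripts split the replicates of some groups. The Paneth list took 0.00804% of UMIs in Bmi1-GFP+ replicate 1 and 3.61% in replicate 2, which held 0 and 4 Paneth-like cells. Lgr5-eGFP- replicates gave 0.0265% and 2.78% with 0 and 5 Paneth-like cells, Lgr5-eGFP+ replicates 1.70% and 1.77% with 12 and 16, and Prox1-GFP+ Chromium replicates 0.00511% and 0.0127%. Within Bmi1-GFP+ enteroendocrine-like cells, Prox1 was at 138 CPM in the Cck cluster (counting interval 120.5 to 158), 90.0 in the Ghrl, 84.7 in the Pyy, 56.7 in the Sst, 31.5 in the Tph1 and 14.0 in the Gip cluster (5.13 to 30.4).

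Bmi1-GFP+ cells filled the Tph1 and Sst clusters, and Prox1-GFP+ Chromium cells left them nearly empty, with 2 of 131 enteroendocrine-like cells where 64.8 would follow the Bmi1-GFP+ share. A binomial test against too few cells gave 1.3e-35, which covers counting error only, treats cells as independent draws and was run on the pattern that prompted it. Removal by the cell filter was tested on all 278 Prox1-GFP+ Chromium barcodes, where 8.27% passed the Tph1 or Sst UMI limits against 50.6% of Bmi1-GFP+ barcodes, a ratio of 0.164 (upper bound 0.240). This ratio missed the limit set beforehand, and the argument against removal rests on the test added later, in which counting all 15 removed barcodes as such cells would reach 11.6% against 49.4%. The ratio also reflects class shares, since 42.1% of Prox1-GFP+ Chromium and 0.415% of Bmi1-GFP+ cells were tuft-like. In Prox1-GFP+ Chromium libraries 23 barcodes passed, more than the 2 cells and 15 removed barcodes together. Some kept cells past the limits thus lay outside the Tph1 and Sst clusters. A candidate explanation is that the gate follows Prox1 transcript level, since Prox1 in these clusters was 0.394 times that of the other enteroendocrine-like cells of the same Bmi1-GFP+ libraries (interval 0.293 to 0.524; 42.5 against 108 CPM). The Gip cluster had the lowest Prox1 level, and its share of 1.53% in Prox1-GFP+ Chromium against 9.09% in Bmi1-GFP+ cells goes with this explanation, while 16.2% in GemCode cells goes against it as the whole cause. Sex as the whole cause is argued against by GemCode libraries, which had 0 Xist UMIs and Ddx3y at 23.3 CPM and held 0 Tph1 and 1 Sst cell of 130. Reporter line and strain stay open as untested.

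Panel transcripts such as Axin2 were found in enteroendocrine-like cells of Bmi1-GFP+ libraries. At the ratio of 19 to 165 in the remaining 42 cells, 108 Lgr5 UMIs would go with the 940 UMIs of the other 11 panel genes. In the 627 cells 0 were seen. The 19 UMIs lay in 5 cells, and resampling the 42 cells put the needed number at 21.5 to 189.8, with 75.8 in replicate 1 and 29.4 in replicate 2. However, only 9 of the 42 cells were stem-like. The 940 UMIs also include Prox1, with 60 UMIs in the Tph1 and Sst clusters and 259 in the others, and Prox1 averaged 1.91 CPM in Lgr5-eGFP+ libraries. The needed number is thus not one for stem-cell RNA, and this test cannot decide on free RNA. Doublets with stem cells would bring 80.7 Lgr5 UMIs beside 129 of Axin2, at the ratio of 492 to 786 in 745 stem-like cells (72.1 to 90.3 over resampled cells). As a hypothesis, part of this panel RNA may be transcribed in the endocrine cells themselves. It was found and tested on the same data, and free RNA stays open as another source. The tests first planned, on the presence of Lgr5 and Olfm4, had 0 and 2 UMIs and could decide nothing.

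The tuft-like share was higher in GemCode than in Chromium Prox1-GFP+ libraries. Among cells with at least 5000 UMIs 132% of the difference was left (57.6 against 43.8 points). Kept cells below that limit thus did not make up the difference. The limit raised the tuft-like share to 94.9% and 95.3% in GemCode libraries and lowered it to 43.7% and 31.25% in Chromium libraries. It removed unlike cells on platforms with unlike UMI lengths, so other effects of depth or cell calling cannot be excluded. Xist averaged 2371 CPM in Chromium libraries and 0 in GemCode libraries (limit 0.374), and Y-linked Ddx3y had 0 UMIs and 23.3 CPM. These values show female cells in the Chromium and male cells in the GemCode libraries, and so different animals. Different animals are a candidate explanation, and whether they changed the tuft-like share was not tested. Platform, UMI length, sequencer and animals all changed together, so their effects were not separated.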
